A study of Drosophila melanogaster with 6 samples.

How the data were processed

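Total RNA of Drosophila melanogaster embryos was compared on 6 dye-swapped arrays that carried mutant and wild-type RNA in different dyes. The mutants were doubly heterozygous for engrailed and gooseberry-neuro, and the wild type was the Oregon strain, per the labels. Each of 3 biological replicates was hybridised on 2 arrays, once with the mutant RNA in Cy3 and once in Cy5. The series' own design text calls the replicates independently selected. Embryo stage, alleles and stock background are not given in the sources used here.

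Per the file headers, spots were quantified with ArrayVision, and the deposited intensity of each dye is a volume (pixel level times square mm) with a local background and a flag beside it. The authors also deposited a background-subtracted intensity in which negative differences were set to 0. A further table of the authors holds 1 log2 ratio per spot and array; limma is named in the submitters' processing notes, without a version or step. Its rows follow another spot order than the scanner tables. With 12 rows and 2 columns of printed blocks, ordered by block column, block row, spot column and spot row, its values followed the log2 ratio of Cy3 over Cy5. Over bright spots the correlation was 0.993 to 0.996 on arrays with the mutant in Cy3, and -0.991 to -0.992 on the others. The deposited log2 ratios are therefore mutant over wild type on all 6 arrays. Their median per array lay between -0.03 and 0.03, and they were used only as an alternative. How the authors corrected background and normalized is not given in the sources used here. All columns used belonged to the samples of this series.

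The array has 15744 spots. The files carry no spot names, so control spots were recognised by their layout, after a first fit had been plotted with them included. The first 16 positions of row 1 repeated in all 24 blocks, with a median SD of log2 level over blocks of 0.24, against 1.29 at other positions. Runs of 8 neighbouring spots at the end of each block held 1 level each, with a median SD of 0.08, and stretches beside them were blank. Without spot names, some of these runs could be repeated gene probes. Together 1056 spots were read as controls or blanks, among them all 52 positions without a deposited log2 ratio on 5 of the arrays. They had weight 0 in the loess fit and were left out of every test. A further 60 probes flagged on at least 1 array were left out, which left 14628 tested probes. Kept as probes, 86 of the control spots would have passed the threshold, and the first fit had called 2441 spots.

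Background was corrected with normexp in limma 3.58.1 under R 4.3.3, and each array was normalized by loess, with no step between arrays. The plan set an offset of 50, a value meant for pixel levels, whereas the deposited intensity is a volume with medians per dye and array between 1.69 and 6.62. Volumes were therefore divided by an assumed spot area of 0.02 square mm before the offset, which equals an offset of 1 on the deposited scale. This departure was decided before any call had been counted. It matters: with 50 added to the volumes as deposited, 51 probes passed in place of 2609. Any offset pulls ratios of dim spots toward 0, so fold changes are understated there. In simulated arrays with known changes, the fitted log2 ratio had a median of 0.79 for 2-fold and 1.71 for 4-fold changes among the brighter probes.

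Log2 ratios were turned to mutant over wild type, both arrays of a replicate were averaged, and the 3 values were tested against 0 with lmFit and eBayes. Probes with a Benjamini-Hochberg adjusted p under 0.05 over the tested probes were called. Values are mean ± SD over n = 3 replicates. On simulated data, 16 of 100 probes changed 2-fold and 58 of 100 changed 4-fold were called, with 3 calls among 14428 unchanged probes. Only 200 probes were changed there, whereas 17.8% of the tested probes were called in the data, so these shares need not carry over. Noise was drawn apart for each probe, so false calls from differences shared by many probes could not appear. The number of arrays limits the precision. A probe counted as above background on an array at 2 or more times its local background. Where one genotype was not well above background on any array, the ratio is a bound. It sets the brighter genotype's mean against, per array, the higher of the dim probe's signal and the lowest signal among probes above background, after loess and Aquantile scaling.

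Gene names came from the platform annotation, which lists 1 gene for 67 probes, several for 1 probe and none for 15676 of the spots, controls included. The 67 probes stand for 63 genes. The gene IDs of 62 probes matched the reference gene table (assembly Release 6), which was used for current symbols and gene order, and 5 kept the annotation's symbol. The probe with the highest mean level stands for a gene with 2 probes. Named are engrailed, invected, gooseberry and gooseberry-neuro, the 10 genes with the largest fall and the 10 with the largest rise past the threshold in 1 direction on all 6 arrays, and, from each of 8 lists on segmentation and the nervous system, up to 4 members past the threshold or else the 2 with the smallest p. Lists past a whole-list test and called neighbours of the targeted genes were to be named too. Where fewer than 5 passed in a direction, the smallest p filled the places up to 5. None of the 67 probes is annotated to engrailed, invected, gooseberry or gooseberry-neuro, so these genes and their neighbours are not analysed here. Of 39 gene lists, none reached 5 measured genes, so tests of whole lists were not run.

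The groups, tests, naming rule, gene lists and 15 of the alternative settings were fixed before the data were examined. They vary background correction, normalization, dim probes, the dye swap, probes per gene, the variance prior, the source of the ratios and the replicates. A further 5 were added after seeing the data. Not run were the median over spots of a probe, since the tables list each probe at 1 spot (the design text speaks of triplicates per array, which were not found outside the repeated control positions), and slide or scan date as a block, since the scanner tables give neither.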

Results

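Embryos doubly heterozygous for engrailed and gooseberry-neuro, which encode a homeodomain and a paired-class transcription factor of the segmented embryo and its nervous system, were compared with wild-type Oregon embryos. RNA of both genotypes was hybridised together on 6 arrays, as 3 biological replicates with a dye swap each. Signal was above background for 39.8% to 64.6% of the probes in the mutant channel and 38.6% to 64.2% in the wild-type channel. The comparison asks which transcripts differ in level between the genotypes. Genotype and stock form 1 contrast here, because the labels name no control of the mutants' own background. Embryo stage is not given, so a difference in stage between the genotypes would be part of the same contrast. The engrailed and gooseberry-neuro transcripts themselves were not analysed here, so the labels have no check from the targeted genes.

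Among the 63 genes with a name, 12 were lower and 3 were higher in the mutants. The split was uneven: of 15 detected genes next to a centromere, 9 were lower and 0 higher past the threshold. Among 23 other detected genes, 3 were lower and 3 higher, a grouping made after the values were seen. The largest fall was in eIF4B, a translation initiation factor, which was 5.72-fold lower on 1 probe (log2 ratio -2.51 ± 0.36, n = 3, adjusted p = 0.00706) and 5.51-fold lower on the other (-2.46 ± 0.20, adjusted p = 0.00706). Parp1, which encodes poly(ADP-ribose) polymerase, fell by 1.96 on the log2 scale (SD 0.47, adjusted p = 0.0101). Glycogenin (Gyg), the primer of glycogen synthesis, was 4.30-fold lower on its brighter probe (-2.10 ± 0.50, adjusted p = 0.00996), but its other probe was at -0.26 ± 0.37 (adjusted p = 0.371), so its probes disagree. The 3 rises were smaller, between 1.34-fold for AMPKalpha and 1.40-fold for RpLP0-like.

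The other falls lay between 2.24-fold and 1.46-fold. Gfat1, an enzyme of hexosamine synthesis, was at -1.16 ± 0.46 (adjusted p = 0.0231), and the chitinase gene Cht10 at -1.15 ± 0.63 (adjusted p = 0.0438). The vesicle trafficking gene lt (light) was at -1.15 ± 0.29 (adjusted p = 0.0125). Among signalling genes, cta (concertina), a G protein alpha subunit, was at -1.06 ± 0.22 (adjusted p = 0.0113), and Gprk1, a kinase of G protein-coupled receptors, at -0.96 ± 0.06 (adjusted p = 0.0086). The gene vsg was at -0.81 ± 0.24 (adjusted p = 0.0192), and SNF4Agamma, the gamma subunit of AMP-activated protein kinase, at -0.75 ± 0.25 (adjusted p = 0.0226). Dbp80 and p120ctn also passed the threshold and are named here after their values were seen. The RNA helicase gene Dbp80 was at -0.70 ± 0.16 (adjusted p = 0.0178) on 1 probe and -0.64 ± 0.17 (adjusted p = 0.0216) on the other, and p120ctn, a catenin of cell junctions, at -0.55 ± 0.26 (adjusted p = 0.0495). All 12 genes were lower on all 6 arrays.

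RpLP0-like, a relative of the ribosomal stalk protein P0, was at 0.49 ± 0.10 (adjusted p = 0.0284). Nop60B, the pseudouridine synthase of small nucleolar ribonucleoproteins, was at 0.47 ± 0.03 (adjusted p = 0.0241), and AMPKalpha, the catalytic subunit of AMP-activated protein kinase, at 0.42 ± 0.13 (adjusted p = 0.0438). These genes were higher on all 6 arrays. FucTC, a fucosyltransferase gene, was at 0.51 ± 0.25 (adjusted p = 0.0555) and CG11837 at 0.39 ± 0.21 (adjusted p = 0.0852), and neither passed the threshold. FucTC passed in 5 of 19 other settings, with adjusted p down to 0.0223 with all 6 arrays and replicate as a block. CG11837 passed in 2 of 20, in that fit (adjusted p = 0.03) and without replicate 1 (0.51, adjusted p = 0.0488). FucTC was above background on 4 arrays in the mutant channel and on 1 in the wild-type channel.

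Without replicate 2, none of the 15 genes passed in limma, with log2 ratios then of -2.72 for eIF4B and -2.22 for Parp1 (adjusted p = 0.131 for both), -1.29 for lt and 0.49 for Nop60B. The call of Nop60B also ended without replicate 1 (0.46) or 3 (0.47), that of AMPKalpha without replicate 1 (0.36), and that of RpLP0-like without replicate 3 (0.46). The call of p120ctn ended without any 1 replicate, at -0.51, -0.69 and -0.44 without replicates 1, 2 and 3. With the offset on volumes as deposited, all 15 calls ended. Of 20 other settings in all, the call ended in 12 for p120ctn, 9 for AMPKalpha, 7 each for Cht10, RpLP0-like and Nop60B, 3 for vsg and 2 for each of the others.

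**Figure D1:**
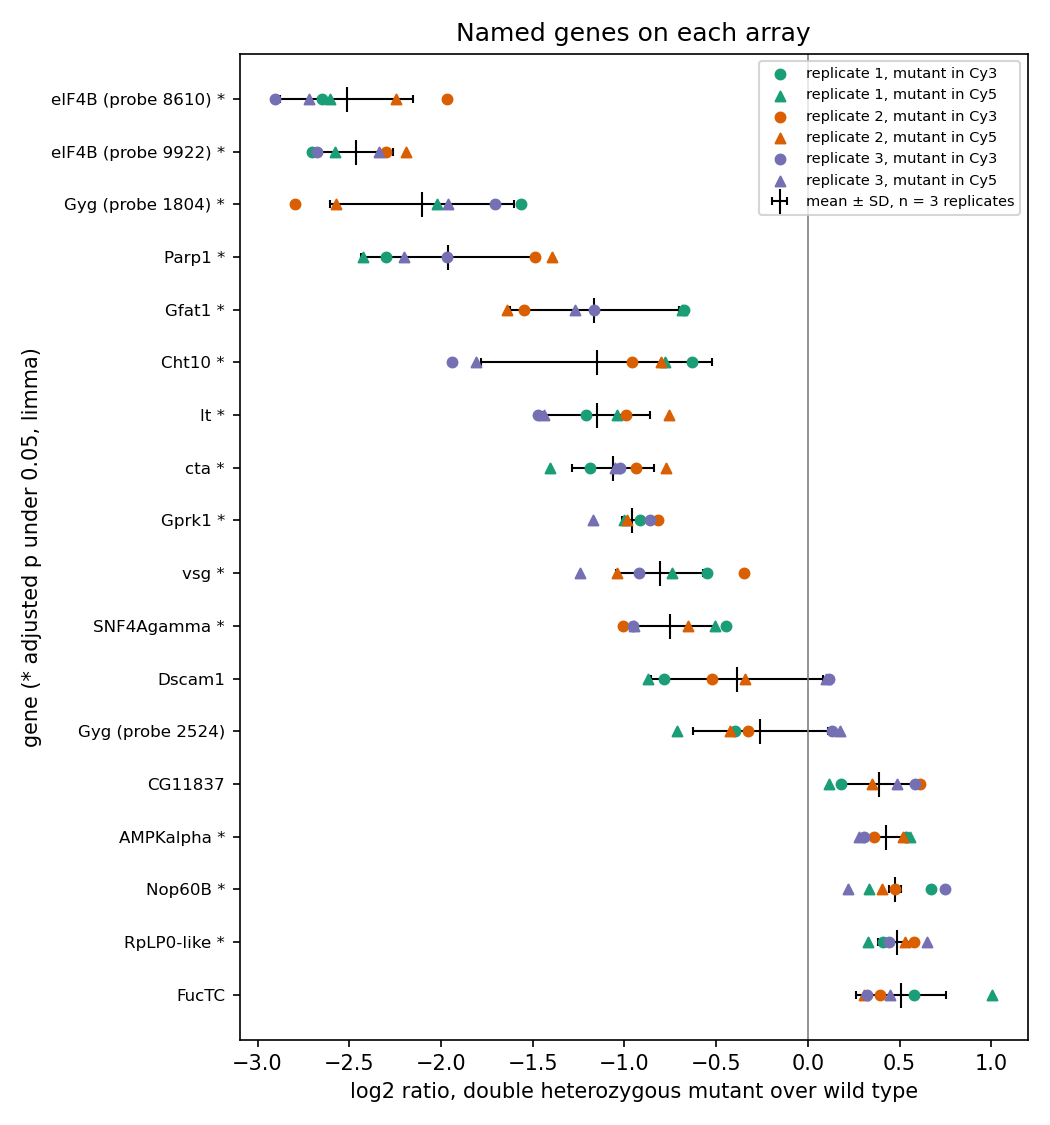
Log2 ratio of mutant over wild type (x axis) for genes taken by the naming rule and above background in both genotypes on at least 1 array (y axis), 1 point per array, coloured by replicate and shaped by the dye of the mutant RNA; bars are the mean ± SD of 3 replicates and an asterisk marks an adjusted p under 0.05 in limma. The eIF4B probes average -2.51 and -2.46, whereas the Gyg probes lie apart at -2.10 and -0.26.

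Nervous system genes were scarce among the named probes, and none passed the threshold with all replicates. Dscam1, an axon guidance receptor and the only measured gene of that list, was at -0.38 ± 0.47 (adjusted p = 0.273), with 2 replicates below 0 and 1 above. It was above background on only 2 arrays in the mutant channel and 4 in the wild-type channel. Of 19 other settings it passed only without replicate 3 (-0.63, adjusted p = 0.0345) and was at -0.16 without replicate 1. Of the mature neuron and synapse list, acetylcholinesterase (Ace) and Snap25 were not well above background in the mutants on any array, and above it in wild type on 1 array each. Ace had a mean bound of 1.03-fold lower in the mutants, above 0 on the log2 scale in replicate 2 only, and Snap25 has no fold. The adjusted p of Ace in limma, 0.221, is that of its measured ratio, not of the bound. The lists of segment polarity genes, Engrailed targets, neuroblasts, neuronal transcription factors, glia and the ventral midline had 0 named members.

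Of 39 lists, 6 had a measured gene, with 10 genes in all, of which only RpLP0-like passed the threshold over all probes. The 3 measured muscle genes were named after their values were seen. The troponin T gene up was at -1.06 ± 0.65 (adjusted p = 0.0572), Mlc1 at -0.95 ± 0.95 (adjusted p = 0.166) and Prm at -0.47 ± 0.29 (adjusted p = 0.0882). None of the 3 passed over all probes, and 2 did adjusted over the list alone. Without replicate 1 all 3 passed: up at -1.42 (adjusted p = 0.00671), Mlc1 at -1.43 (adjusted p = 0.0174) and Prm at -0.63 (adjusted p = 0.0304). All 3 also passed with all 6 arrays and replicate as a block (adjusted p = 0.00532 for up, 0.0418 for Mlc1 and 0.0203 for Prm). Of 20 other settings, these included, up passed in 8, Prm in 3 and Mlc1 in 2. The block fit has the same 3 biological replicates, and its p is too small where dye-swapped arrays resemble each other more than its 1 correlation. Mlc1 was at -0.48 without replicate 3. The RpL and RpS name pattern also took RpL15, at -0.23 ± 0.23 (adjusted p = 0.29), and 1 of its 2 genes passed adjusted over the list alone. The mitochondrial ribosomal gene mRpS5 was at 0.08 ± 0.09 (adjusted p = 0.623), and the histone gene His2B:CG40461 was not well above background in either genotype. Adjusted over the 63 named genes alone, 20 genes passed.

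Over all 14628 probes, 2609 passed the threshold (17.8%), 1064 of them higher and 1545 lower in the mutants. A change of at least 2-fold was seen for 144 higher and 761 lower probes. The median size of a called change was 0.83 on the log2 scale, or 1.77-fold, and 2604 of the called probes had 1 direction on all 6 arrays. Calls lay among bright probes, with 1454 in the brightest 25% and 7 in the dimmest 25%. The offset pulls ratios of dim probes toward 0, and 3952 tested probes were above background in neither channel on any array. This pattern therefore need not come from the genotypes. Most probes carry no gene name here. Probe 12910 was 11.9-fold lower (-3.57 ± 0.21, adjusted p = 0.00706) and probe 9990 was 8.46-fold lower (-3.08 ± 0.20, adjusted p = 0.00706). Probe 12924 was at least 7.60-fold higher and probe 2831 at least 4.99-fold higher in the mutants, since wild type was not well above background on any array for either. Their adjusted p in limma, 0.0203 for probe 12924 and 0.0141 for probe 2831, are those of the measured ratios, not of the bounds. These bounds are means over replicates that varied: on the log2 scale they were 3.97, 3.10 and 1.71 for probe 12924 and 3.07, 2.22 and 1.67 for probe 2831.

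Without replicate 2 limma called 0 probes, although 2898 had an unadjusted p under 0.05, against 4676 with all replicates. Both arrays of a replicate correlated at 0.87 to 0.95 across probes, and arrays of different replicates at 0.58 to 0.79; probes are not independent replicates. With the offset on volumes as deposited, 51 probes passed, 41 higher and 10 lower.

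**Figure D2:**
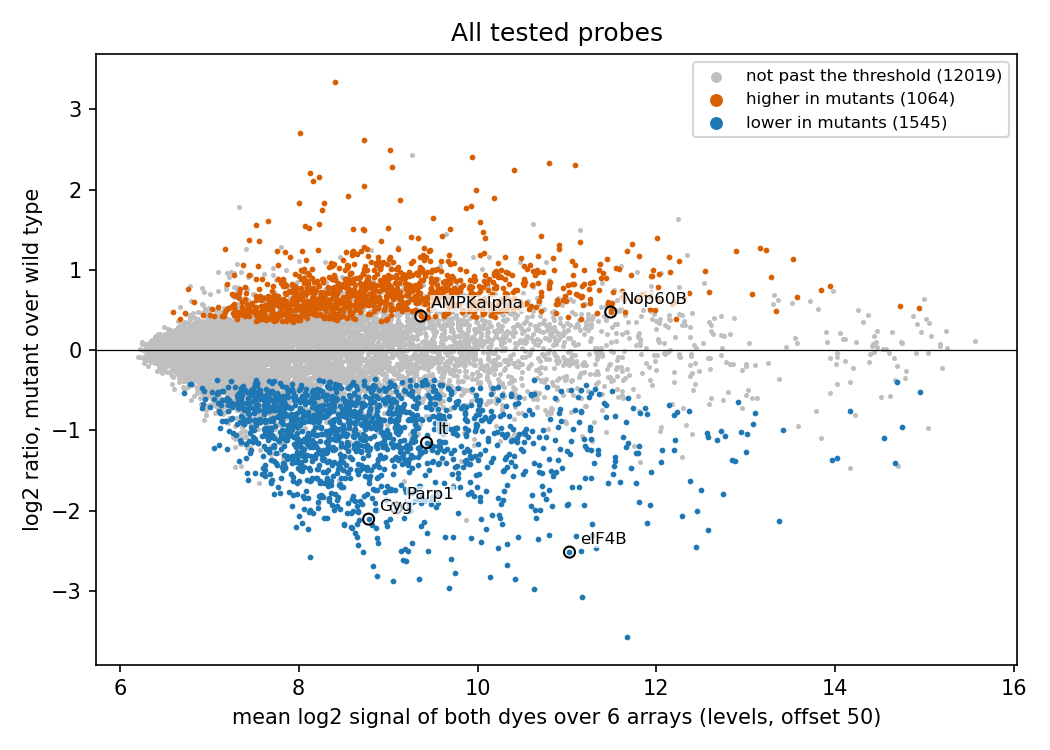
Log2 ratio of mutant over wild type (y axis) against the mean log2 signal of both dyes over 6 arrays (x axis, pixel levels with the offset of 50), 1 point per tested probe; orange and blue points passed an adjusted p of 0.05 in limma. The 1064 higher and 1545 lower probes lie mostly at higher signal, and eIF4B is among the lowest ratios.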

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

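Tests with 50 added to the volumes as deposited, loess within printed blocks, the deposited background-subtracted volumes, control spots kept, and only probes detected on all 6 arrays were chosen after the results were seen. In the 20 settings no called named gene changed direction, nor did any probe called there and in the main analysis. Log2 ratios are unchanged with Aquantile scaling, the dimmest 25% left out, replicate as a block, the other variance prior and detected probes only. No direction could change there. Leaving out 1 replicate or dye orientation could not reverse the 15 named genes or 2604 called probes, with 1 direction on all 6 arrays. The mean over probes changes only genes with 2 probes. Of the 15 named genes past the threshold, 9 lost the call only without replicate 2 and with the offset on the deposited volumes, and 6 (vsg, Cht10, p120ctn, Nop60B, RpLP0-like and AMPKalpha) in other settings too. The 9 include Gyg, which was at -1.18 with its 2 probes averaged (adjusted p = 0.0145 in limma), against -2.10 on the brighter probe. Leaving out 1 replicate gave 0 to 3184 called probes (0 to 1202 higher, 0 to 1982 lower), 0 to 18 named genes and 0 to 4 list genes; the 0 in each case came without replicate 2, where 2898 probes had an unadjusted p under 0.05. Fewer replicates are part of that setting, but dropping replicate 1 or 3 left 2450 and 3184 calls, and the cause was not tested. All 6 arrays with replicate as a random block and a dye term gave 3932 probes (1611 higher, 2321 lower), 25 named genes and 4 list genes. The block and the dye term were not run apart, and this fit adds no biological replicate. The offset on the deposited volumes gave 51 probes (41 higher, 10 lower, so 19.6% lower against 59.2%), 0 named genes and 0 list genes; it exceeds most signals and shrinks their ratios, and 3088 probes had an unadjusted p under 0.05. With control spots kept, 2441 spots passed. The list genes past the threshold, 1 in the main analysis, were 0 without background correction and with the deposited log2 ratios, 2 with offset 16, without the dimmest 25% of probes and among detected probes, and 3 on arrays with the mutant in Cy5; the cause was not tested. The other counts of called probes stayed within 1.5 times, including 2077 at 1.5-fold or more. Signal limits the dim probes: 3952 were not above background in either channel on any array, and 3 of these were called. Each array sets mutant against wild type, so the main analysis is a paired one, and no unpaired analysis was run. Whole-list tests with an estimated correlation or fry, the median over spots, and slide or scan date were not run.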

Other observations

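All tests in this part except the exchange of mutant and wild type within replicates were chosen after the results were seen.

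The beta subunit gene of AMP-activated protein kinase, alc, was at -0.29 ± 0.56 (adjusted p = 0.48). Among genes of small nucleolar ribonucleoproteins, Nop60B passed at 0.47 ± 0.03, while NHP2 was at 0.28 ± 0.20 (adjusted p = 0.17) and Nop56 at 0.00 ± 0.11 (adjusted p = 0.982). Of mitochondrial enzymes, mAcon1 was at -0.64 ± 0.33 (adjusted p = 0.0502), Idh3b at 0.18 ± 0.38 (adjusted p = 0.563) and Mccc2 at 0.54 ± 0.44 (adjusted p = 0.124). CG13323 had replicates in opposite directions, at 1.60, 2.39 and -0.71. The 6 named Y-linked genes were above background in 0 channels on any array.

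Exchanging mutant and wild type in 1 replicate at a time gave 0 called probes each, against 2609 as labelled, so 1 of 4 arrangements reached that count and the highest of the others was 0. The arrangements are too few for a share under 0.05.

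The ratio of eIF4B was low on both of its probes. Dye bias is argued against by a mean log2 ratio of -2.37 or lower for each probe in each dye orientation, and a defect of 1 spot by the log2 ratio of -2.46 on the other probe. A sequence variant in 1 of the stocks could lower hybridisation without a change in transcript level, and it stays open. The probes differed by 0.052 in log2 ratio, less than their spread between replicates, but they may share their sequence, which was not used here. An effect of the genotype on eIF4B was not tested apart from these.

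Named genes next to a centromere were mostly lower in the mutants. The 15 detected genes within the nearest 44 of a chromosome arm in annotation order had a median log2 ratio of -0.70, with 9 past the threshold lower and 0 higher, against a median of 0.00 for 23 others, with 3 lower and 3 higher. All probes of that brightness had a median of -0.0429, but the loess fit on each array sets such a median near 0 in advance. It therefore cannot decide whether a shift shared by probes of that brightness played a part. Of random lists of such probes, 95% had a median between -0.49 and 0.33, but the 15 genes were grouped after their values were seen. Noise independent between arrays is argued against by 12 of the 15 being lower on all 6 arrays. Such noise would give 0.594 of all 38 detected named genes. Of the 23 others, 8 were also lower on all 6 arrays, so such counts are not particular to genes next to a centromere. Noise shared by both arrays of a replicate, which correlated at 0.87 to 0.95, is not covered. The mean difference was -0.69 (-0.57 without eIF4B, -0.16 with the offset on the deposited volumes). Its two-sided permutation p was 0.00554, but the grouping was noticed in these same genes, so the choice of named probes stays open. That p takes the genes as independent and does not measure spread between replicates. In replicates 1, 2 and 3 the mean difference was -0.92, -0.55 and -0.59. The stock background could produce the same difference of -0.687 and cannot be told apart from the mutations, because the labels name no control of the mutants' background.

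Arrays of 1 replicate resembled each other more than arrays of different replicates did. Noise of single arrays or dyes as the whole source is argued against, since differences between replicates seen with the mutant in Cy3 recurred with it in Cy5, with a correlation across probes of 0.650 to 0.845; a step shared by both arrays of a replicate stays open. Embryo pools may have differed in age: the muscle genes Mlc1 (0.01, -0.97 and -1.89 in the 3 replicates) and up (-0.34, -1.58 and -1.26) spread more than 94.5% and 91.6% of probes of like brightness, but Prm (-0.14, -0.71 and -0.55) more than only 59.9%. The median, 91.6, lies between the bounds set for and against this explanation, so age cannot be told apart from other differences between pools. No biological explanation was tested further.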
